A study of Gadus morhua with 20 samples.

How the data were processed

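RNA was measured in liver samples of Baltic cod, 10 labelled control and 10 labelled infected, and the group and replicate number of each library were taken from its label. The labels do not say that each sample came from a separate fish, so p-values measure the spread between these samples. The labels name no sex, size, catch or batch, and no covariate was used. Per the labels' protocols, total RNA was extracted from homogenised liver, treated with DNase and made into libraries from 500 ng with an Illumina TruSeq stranded mRNA kit.

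Per the submitters' processing notes, the authors used CASAVA, TopHat2 2.0.5, SAMtools 0.1.18, HTSeq 0.5.3p9 and DESeq before the files were deposited. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Each deposited file holds raw read counts per transcript identifier, with no normalisation, as judged from the values, which are whole numbers whose totals differ between libraries. Without the strand setting and the annotation, transcripts that overlap, lie antisense to each other or share reads with near-identical copies cannot be recognised, and the value of any single identifier is uncertain to that extent. A table of the whole series has 20 columns whose names match no label, and it was not used.

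None of the identifiers matched the gene table supplied with the data (0 matched), so the files do not pair them with gene names. The 36 gene lists fixed before the data were examined, covering immune, metabolic, stress, growth and cell type markers, therefore had 0 lists that could be tested. The rule for naming transcripts, fixed at the same time, required a gene name or description, and no transcript met it. In its place, the raised transcript with the highest fold and the 2 lowered transcripts with the highest fold were named, among those past the threshold with a mean of at least 1 CPM. GAMO_00027785-RA was added as the second raised transcript after its values were seen.

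Counts were analysed in R 4.3.3 with edgeR 4.0.16. Identifiers were kept by filterByExpr with the group as the design, which left 13259 holding 99.4% of counts. TMM factors, the quasi-likelihood fit with robust dispersion and a two-sided quasi-likelihood test of infected against control were used, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE given for a log2 fold change is its absolute value divided by the square root of the test's F statistic, not a fitted standard error. CPM values use the library totals of the kept identifiers multiplied by TMM factors, and log2 CPM adds a prior count of 2. Library properties were compared by a two-sided permutation test of the difference in means with 100000 resamples, or by exact enumeration where a group had fewer than 10 libraries. They were adjusted over the family of 5. Shares of counts in single libraries carry 95% Wilson intervals, and a count of 0 was taken to allow up to 3 counts. The totals of 7865148 to 12813825 counts per library set the precision of these values.

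The procedure was tested on simulated counts for 13315 transcripts with the means and library sizes of the 10 and 10 libraries. Of these, 50 were changed at each of 4 folds. It recovered 4% of 1.5-fold, 44% of 2-fold, 84% of 4-fold and 82% of 8-fold changes, and 9 of its 116 calls were false. With so few changed transcripts the Benjamini-Hochberg adjustment is stricter than in the real comparison, so these recoveries do not carry over to it. Replicates were compared in pairs. In each group the 45 pairs differed by more than sampling noise (lowest chi-square per degree of freedom 35.1 in controls and 35.8 in infected). No library was therefore a second reading of another, and all 10 libraries per group were counted. This check cannot show that they came from separate fish. Correlations of log2 CPM between replicates, across transcripts, which are not independent replicates, ran from 0.849 to 0.948 in controls and from 0.859 to 0.951 in infected livers.

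Alternatives chosen before the data were examined were the DESeq2 1.42.0 Wald test, RLE factors, no filter, a filter at a mean of 1 CPM, non-robust dispersion, limma 3.58.1 voom with sample quality weights, a block on replicate number, up to 3 surrogate variables from sva 3.50.0, and leaving out each library in turn. Added after the data were seen were leaving out the 5 libraries with over 1% of counts in GAMO_00027785-RA, that transcript as a covariate, library totals without TMM, thinning to the smallest total, shares of counts with a set of 6 transcripts left out, and all alternatives for library properties. Library properties, intervals and plots were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.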

Results

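The data were RNA sequencing counts from the liver of Baltic cod (Gadus morhua), a gadoid fish. They covered 10 control liver samples and 10 liver samples infected with Contracaecum osculatum, a nematode whose larvae lodge in the cod liver. Below, a liver means 1 such sample, which the labels do not state to be from a separate fish. Each library was a poly(A)-selected, strand-marking preparation from 500 ng of total RNA, read on an Illumina HiSeq2500. Each file gave 83505 transcript identifiers with 1 whole-number count each, and 36480 of these had no count in any of the 20 libraries. The total count per library ran from 7865148 to 12813825 in controls and from 9062798 to 12289458 in infected livers. The means of 9889330 ± 1350350 (SD, n = 10) and 10494200 ± 992608 (SD, n = 10) differed by 604896 (two-sided permutation test, p = 0.275). Without control 7 the difference was 929840 (exact permutation p = 0.0503) and without control 10 it was 379987 (exact permutation p = 0.467).

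The single comparison of the design asked how the liver transcriptome differed between infected and control cod. Infected livers differed from control livers across a large part of what the liver expressed: of 13259 transcripts tested, 2465 were higher and 2429 were lower in infected livers. Transcripts that fell made up 46.7% ± 3.39 (SD, n = 10) of all counts in control livers and 23.4% ± 11.4 (SD, n = 10) in infected livers. Those that rose went from 6.00% ± 1.16 (SD, n = 10) to 32.3% ± 23.0 (SD, n = 10), a share carried in large part, in infected 1, 2, 7 and 8, by 5 raised members of a set of 6 transcripts described below. With that set left out of the counts and the totals, transcripts that fell held 46.8% ± 3.00 in controls and 27.5% ± 6.17 in infected livers, and those that rose 5.65% ± 0.374 and 16.6% ± 2.47 (SD, n = 10 each). Without control 6 and infected 1, 2, 7 and 8, the former held 47.6% ± 1.81 (SD, n = 9) and 32.0% ± 2.16 (SD, n = 6), and the latter 5.65% ± 0.384 (SD, n = 9) and 15.5% ± 0.947 (SD, n = 6). These lists were called on the same libraries, so the direction of their shares is not independent of the calls. Among the 140 transcripts averaging over 1000 CPM (counts scaled to a common library size), 55 fell and 14 rose, whereas among the 5192 between 10 and 100 CPM, 903 fell and 1220 rose. The 14 include the 5 raised members of the set of 6, which reached this mean through the libraries rich in them. With library totals in place of TMM factors, 35 fell and 12 rose in the former class and 664 fell and 899 rose in the latter. Without control 6 and infected 1, 2, 7 and 8, 40 fell and 11 rose in the former and 742 fell and 1014 rose in the latter. The files do not pair their identifiers with gene names, so the changed transcripts are described by number, abundance and identifier.

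The changed transcripts were called by edgeR's quasi-likelihood test (two-sided) with Benjamini-Hochberg adjustment at 0.05, and the 4894 that passed were 36.9% of those tested. Changes of at least 2-fold were found in 1300 raised and 1234 lowered transcripts, and the remaining 2360 changed by less. At least 4-fold, 389 rose and 203 fell, and at least 16-fold, 60 rose and 16 fell. The median absolute log2 fold change of the changed transcripts was 1.02, while the median over all tested transcripts was -0.0049. The common biological coefficient of variation between livers of one group was 0.448.

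The first principal component of log2 CPM, holding 33.2% of the variance, separated the groups without overlap, and the second held 15.7%. Infected 1, 2, 7 and 8 lay apart from the other infected livers on both components. On the first they lay at 58.8 to 73.7 and the others at 34.9 to 47.8. On the second these ranges were 23.1 to 56.3 and -51.2 to -13.2, while controls ran from -47.1 to 43.5. At 456 transcripts every infected liver lay above every control liver, and at 272 every infected liver lay below every control liver, where chance would give 0.0718 in each direction. With library totals in place of TMM factors these numbers were 214 and 192. Without control 6 and infected 1, 2, 7 and 8, the 5 libraries with over 1% of their counts in a single transcript named below, they were 795 and 487, against 2.65 by chance.

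**Figure D1:**
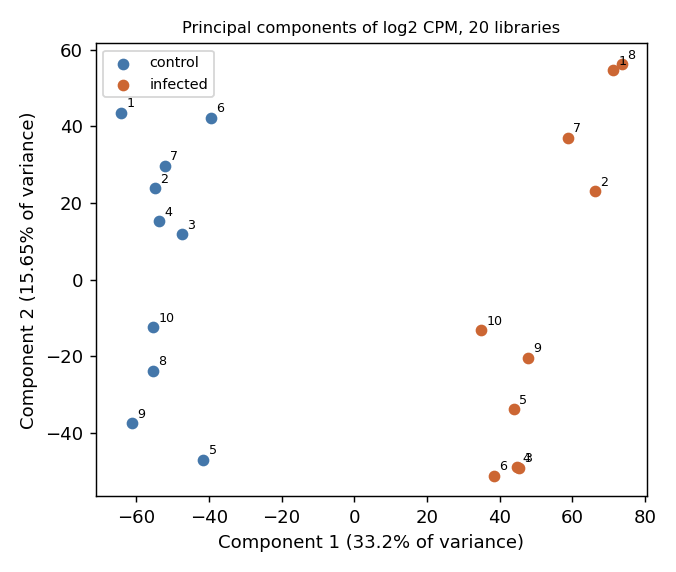
Scores of the 20 libraries on the first and second principal components of log2 CPM (arbitrary units), with points coloured by group and numbered by replicate. Control livers lay between -64.2 and -39.4 on the first component and infected livers between 34.9 and 73.7. Infected 1, 2, 7 and 8 lay above the other infected livers on both components.

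**Figure D2:**
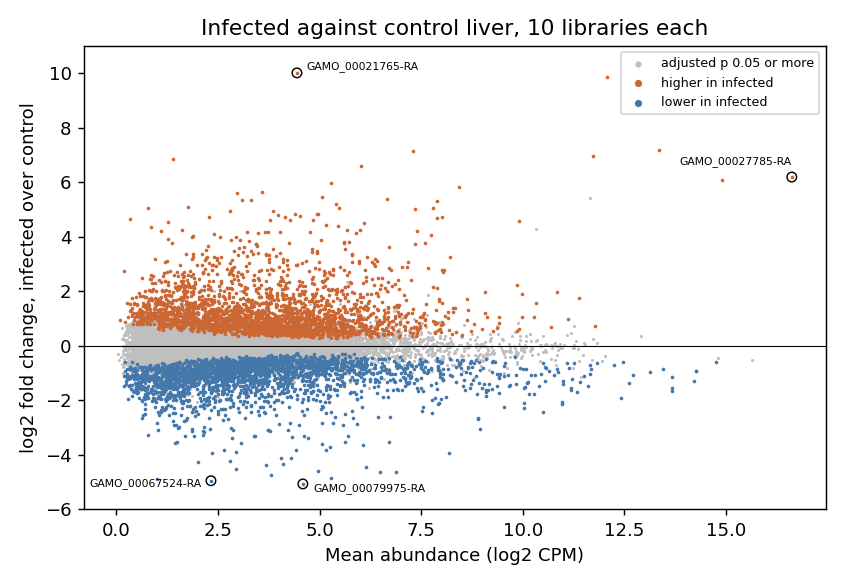
Log2 fold change of infected over control livers (vertical axis) against mean log2 CPM (horizontal axis) for the 13259 tested transcripts, with those past adjusted p 0.05 in colour and the 4 named transcripts circled. The 2465 raised and 2429 lowered transcripts were spread over the whole range of abundance, and the named transcript of highest abundance lay at 6.19.

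The transcript with the highest fold rise was GAMO_00021765-RA, which was close to absent from control livers and present in all 10 infected livers. The 10 control libraries held 3 counts of it in total, with 0 counts in 7 of them, and the 10 infected libraries held 3397, from 31 to 840 per library. A count of 0 allows up to 3 counts, which is between 0.271 and 0.368 CPM over those 7 libraries. The ratio of the summed counts, each divided by the total count of its group, was 1067 (95% counting interval 365 to 5177). That interval covers counting error only and leaves out the spread between livers. Its level was 43.4 ± 50.3 CPM (SD, n = 10) in infected and 0.0275 ± 0.0446 CPM (SD, n = 10) in control livers. Its log2 fold change was 10.01 ± 1.12 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.81e-07). This fitted value depends on the default prior count of the fit, which is not the prior count of 2 used for log2 CPM. Infected 1, 2, 7 and 8 held 89.8 to 119 CPM of it and the other 6 infected libraries 2.56 to 7.04 CPM. Without control 6 and infected 1, 2, 7 and 8 its log2 fold change was 6.81 ± 0.48 (SE).

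The lowered transcripts with the highest fold were GAMO_00079975-RA and GAMO_00067524-RA. GAMO_00079975-RA fell from 46.4 ± 40.5 CPM (SD, n = 10) in control livers to 1.31 ± 3.47 CPM (SD, n = 10) in infected livers. This was a log2 fold change of -5.07 ± 1.09 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000946). It had 0 counts in 5 infected libraries, each of which allows up to 3 counts, or 0.236 to 0.480 CPM over those 5 libraries. Control 7 held 0.164 CPM of it and infected 3 held 11.1 CPM, so the groups overlapped. Without infected 3 its log2 fold change was -7.84 ± 1.05 (SE). GAMO_00067524-RA fell from 9.34 ± 7.74 CPM (SD, n = 10) to 0.271 ± 0.197 CPM (SD, n = 10), a log2 fold change of -4.95 ± 0.57 (SE; the same test, Benjamini-Hochberg adjusted p = 7.78e-07). Every infected library lay below every control library for it.

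**Figure D3:**
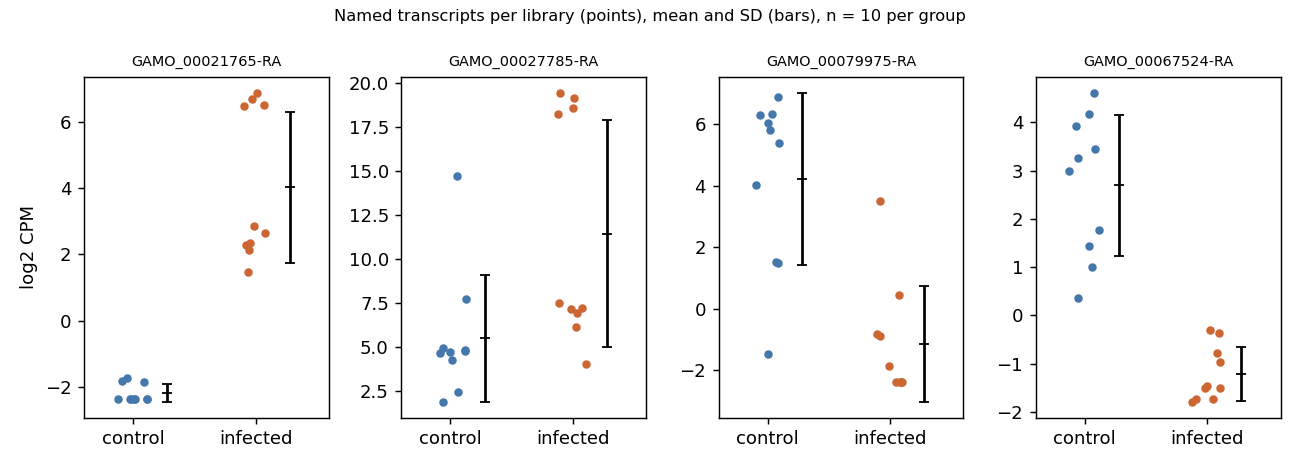
Log2 CPM (prior count 2) of the 4 named transcripts in each library, with points for single livers and bars for the mean and SD of 10 livers per group; the vertical axes differ between panels. Control and infected livers did not overlap for GAMO_00021765-RA and GAMO_00067524-RA and did overlap for the other 2 transcripts.

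A single transcript, GAMO_00027785-RA, took a large share of the whole library in some livers. It held 32.3% of all counts in infected 1 (95% Wilson interval 32.2 to 32.3), 39.0% in infected 2 (39.0 to 39.1), 24.7% in infected 7 (24.7 to 24.8) and 37.5% in infected 8 (37.5 to 37.5). In control 6 it held 2.61% (2.60 to 2.62), and in the other 15 libraries, 6 infected and 9 control, between 0.000324% and 0.0225%. These intervals and limits cover counting error only, since reads copied by PCR are not independent molecules. Its log2 fold change was 6.19 ± 2.26 (SE; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.036). The 5 libraries rich in it were picked by this same value, so leaving them out lowers the difference by construction. The log2 fold change was then 1.44 ± 0.71 (SE) and the adjusted p 0.142, against a range of 8.28e-05 to 0.26 over its 31 alternatives. Without control 6 alone the log2 fold change was 12.20 ± 2.33 (SE).

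It belonged to a set of 6 transcripts that each held at least 1% of counts in at least 1 library and under 0.05% in the median library. The set held 41.6% of counts in infected 1 (95% Wilson interval 41.6 to 41.7), 70.2% in infected 2 (70.1 to 70.2), 36.1% in infected 7 (36.1 to 36.1) and 50.9% in infected 8 (50.9 to 50.9). It held 3.75% in control 6 (3.73 to 3.76) and 0.000564% to 0.0511% in the other 15 libraries.

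The 10 most abundant transcripts of each library held 28.1% ± 2.85 of counts (SD, n = 10) in controls and 36.6% ± 17.7 (SD, n = 10) in infected livers (two-sided permutation test, p = 0.146, Benjamini-Hochberg adjusted 0.243 over 5 library properties). Without infected 2 alone the difference was 4.51 percentage points in place of 8.53 (exact permutation p = 0.292, unadjusted). Without the 5 libraries rich in GAMO_00027785-RA, which take out the 4 infected livers with the highest shares, the direction turned to -4.21 percentage points in infected livers (exact permutation p = 0.005, unadjusted). Identifiers with a count numbered 24343 ± 2597 (SD, n = 10) in controls and 26271 ± 1678 (SD, n = 10) in infected livers (permutation p = 0.0652, adjusted 0.243). Leaving out control 3, 5 or 8 or infected 2 or 8 gave an exact permutation p between 0.0343 and 0.0472, unadjusted, and leaving out the 5 libraries gave a difference of 3233 (exact permutation p = 0.0128, unadjusted). With every library thinned to the smallest total, which does not equalise the counts left to other identifiers where the set of 6 was abundant, they numbered 23486 ± 2195 and 24844 ± 1647 (SD, n = 10 each; permutation p = 0.136, adjusted 0.243), and without the 5 libraries the difference was 2646 (exact permutation p = 0.0178, unadjusted). The distance of a library from its group mean was 0.650 ± 0.105 log2 units in controls and 0.668 ± 0.0738 in infected livers (SD, n = 10 each; permutation p = 0.657, adjusted 0.657). Leaving out control 1, 3, 4 or 9 or infected 2, 5, 8 or 9 moved this difference of 0.0182 by over 1.5 times, to between 0.00192 without control 3 and 0.0394 without control 9 (exact permutation p between 0.291 and 0.961). Without the 5 libraries it was -0.0291 (exact permutation p = 0.571). Over all 20 libraries none of these properties passed the adjustment, and neither did the total count (adjusted 0.344).

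**Figure D4:**
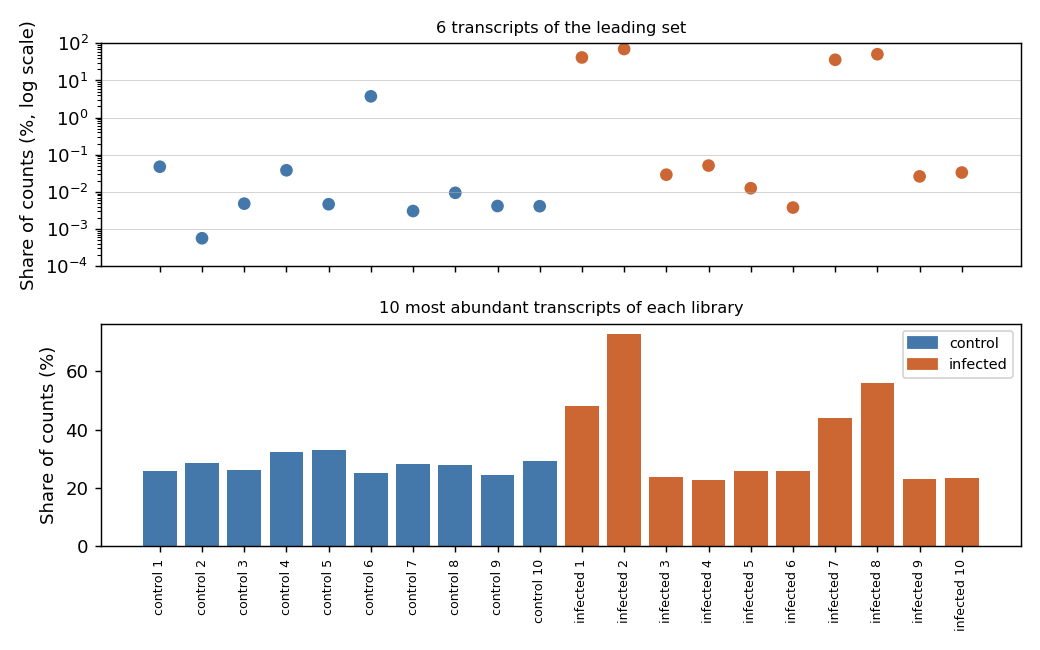
Share of all counts (%) in each library held by the set of 6 transcripts (upper panel, points, log scale) and by the 10 most abundant transcripts of that library (lower panel, bars), coloured by group. Infected 2 had the highest share in both panels, at 70.2% and 72.8%, and control 6 was the only control above 1% in the upper panel.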

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

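In this part, the count of infected libraries below control 6 and the test of infected reads in control 6 were chosen only after the result was seen. Over 20 sets of 10 values, 3 had a library whose gap to its nearest neighbour, divided by the range of the 10 values, exceeded Dixon's 95% critical value. Chance gives about 1 in 20. Of these, 2 are the same signal in control 6, in a transcript and a set picked for their extreme values, to which that rate does not apply. The share of counts in the set of 6 transcripts was 3.75% in control 6, with the nearest control at 0.0476%. The log2 CPM of GAMO_00027785-RA was 14.71 in control 6, with the nearest control at 7.75. The log2 CPM of GAMO_00079975-RA was 3.50 in infected 3, with the nearest infected library at 0.46.

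The set of 6 transcripts took 36.1% to 70.2% of counts in infected 1, 2, 7 and 8 and 3.75% in control 6. In 6 infected libraries the share lay below that of control 6, so the infected label by itself did not set the share. The set was picked for a low share in the median library, which all but fixes such a count. It therefore does not test infection as a cause. A wrong label on control 6 is argued against by the 776 transcripts that separate the other controls from the infected libraries, since control 6 lay nearer the control mean at 722 of them, or 93%. Reads of infected libraries in control 6 are argued against because, of the other 5 transcripts of the set, 3 had a ratio to GAMO_00027785-RA outside the range of infected 1, 2, 7 and 8. What sets the share stays open and was not tested. It may be infection, a difference between fish that the labels do not name, such as sex or maturity, or both.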

How the results depend on the processing

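The alternatives for library properties, and those on the 5 libraries, the covariate, library totals and thinning, were chosen after seeing the data. Under all 32 alternatives the number of changed transcripts stayed within 1.5 times the 4894 of the main analysis, from 3708 (library totals without TMM) to 6697 (DESeq2), with raised transcripts making up 49.2% to 54.9%. The number tested differed, at 13259 in the main analysis, 26028 with DESeq2 and 47025 without a filter, so similar counts are not similar shares. Of the 4894, 97.55% were shared with DESeq2, 73.25% without a filter and 74.32% with library totals. Leaving out 1 library gave 4650 (without control 4) to 4962 (without control 5), with 2305 to 2541 raised and 2269 to 2421 lowered. With a replicate block 4351 changed (2139 raised, 2212 lowered), but the numbers do not pair the samples: residual correlations of same-numbered libraries ran from -0.359 to 0.192, and 2 of 20 libraries correlated best with their own number. Without the 5 libraries 4175 changed, and 70.2% of the 4894 were shared. GAMO_00021765-RA, GAMO_00079975-RA and GAMO_00067524-RA kept direction and call wherever tested (GAMO_00067524-RA was not tested under 1 alternative). Their log2 fold changes ran from 6.81 (without the 5 libraries) to 10.58 (thinned), with 7.16 under voom; from -7.84 (without infected 3) to -4.44 (without the 5 libraries), with -6.69 under voom and -6.63 with the replicate block; and from -5.16 (without infected 5) to -3.90 (voom). GAMO_00027785-RA kept its direction and lost its call under 16 of 31. Its log2 fold change, 6.19 in the main analysis, fell to 3.90 with voom (adjusted p 0.159), 3.92 with the replicate block (0.26), 2.29 with surrogate variables (0.132) and 1.44 without the 5 libraries (0.142). It was 6.13 without a filter (adjusted p 0.114), 5.66 with library totals (0.065), and 5.70 to 6.05 (0.0501 to 0.0584) without control 3, 4, 5, 7, 8, 9 or 10 or infected 1, 2 or 8. The share in the 10 most abundant transcripts turned to -4.21 percentage points without the 5 libraries, which by construction removes the highest infected shares. The planned tests of gene lists were not run, since no list could be matched. With every library thinned to the smallest total 4655 transcripts changed.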

Other observations

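Of the tests in this part, that of a batch following the groups, thinning, the removal of the 5 libraries and the random removals, the counts of transcripts on or off, those following GAMO_00027785-RA and the merging of neighbours were chosen only after the data were seen. Some transcripts were all but silent in some livers and abundant in others. With at most 1 count in at least 5 libraries and at least 50 counts in at least 5, there were 36 such transcripts. Of these, 9 differed between the groups (Fisher's exact test, Benjamini-Hochberg adjusted over the 36), 5 being on more often in infected and 4 in control livers. None of these 36 reached at least 50 counts in all livers of one group and in 0 of the other. This depends on the cut: GAMO_00021765-RA, present in all 10 infected livers, held 31 counts in infected 10.

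Many transcripts varied with GAMO_00027785-RA over all libraries, in a fit that rests mainly on the 5 libraries rich in it. With its log2 CPM as a covariate beside infection, 701 rose and 510 fell with it at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 35.3% of these were among the 4894 changed with infection, against 36.9% of all tested transcripts. In the 15 libraries without control 6 and infected 1, 2, 7 and 8, 4 rose and 0 fell with it. Those 5 libraries were picked by the covariate's own value and hold nearly all of its range, so this removal does not test whether the relation holds among the others. With the covariate, 4130 transcripts changed with infection, and 3538 of them were among the 4894, 3537 in the same direction.

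The 4894 changed transcripts were set against chance and technical causes. Of 100 splits of the 20 libraries into 10 and 10, 1, the real one, gave as many, and the highest other split gave 88. Chance is argued against, though these splits resolve no finer than 1 in 100. They also take the samples as independent, which the labels do not state. Depth is argued against by the 4655 that changed after every library was thinned to the smallest total. Without the 5 libraries rich in a few transcripts 4175 changed, and 70.2% of the 4894 were among them. A difference carried only by those 5 libraries is argued against by these numbers. The 3876 to 4511 changed in 20 random removals of as many others do not measure their part, since each removal kept all 5. A catch, fish or library batch that follows the groups cannot be told apart from infection, because 0 labels name a catch, day, batch, sex or size. Infection may account for the difference as a hypothesis, with such a batch left open.

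Transcripts with consecutive identifier numbers tended to change in the same direction. If the first of a consecutive pair changed, the second also changed in 44.2% of cases, against 41% at a distance of 10 and 37.5% at 1000. Where both of a consecutive pair changed, they went the same way in 75.8% of cases, against 70.4% at a distance of 2, 62.5% at 3 and 49.2% at 10. For consecutive pairs at large, one transcribed unit counted under several identifiers is argued against by a median residual correlation of 0.149 over 3458 pairs, with 3.99% above 0.8. Merging the 138 linked pairs left 13121 units, of which 4837, or 36.9%, changed. The median covers pairs that did not both change, and the share going the same way was not recomputed after merging. For pairs that both changed, one unit under several identifiers therefore stays open. Whether numbering follows position in the genome was not tested, and neighbouring genes or duplicated genes that respond alike may remain as explanations.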
